A study of Rattus norvegicus with 8 samples.

How the data were processed

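Whole testis RNA of rats was hybridised to Affymetrix Rat Genome 230 2.0 arrays, 1 array per sample, in 3 groups: untreated (3 arrays), 8 h after a single oral dose of Adjudin of 50 mg/kg (2 arrays) and 4 d after it (3 arrays). Groups were taken from the sample titles, because the description field names normal testis for all 8 samples. Per the labels' protocols, RNA was extracted from 0.1 g of frozen testis and 5 µg of total RNA was turned into biotin-labelled cRNA. No vehicle group is named, and the labels give the number per group without stating that each array came from a separate animal, so p-values measure only the spread between these samples, which may be technical.

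The deposited values are MAS 5.0 signal intensity per probe set on a linear scale, per the labels, and the 2% trimmed mean of every array's deposited values was 250. The submitters' design text also names GeneSpring 7.2, but the values are neither logarithms nor ratios per gene. Detection calls were not used here. The settings files of the arrays were read only to find arrays that were hybridised together. They gave 3 runs: run 1 held control 1, 8 h 1 and 4 d 1, run 2 held control 2 and 4 d 2 with another version of the fluidics protocol (version 4 against version 5), and run 3 held control 3, 8 h 2 and 4 d 3.

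Each array was multiplied by 1 factor that brought its 2% trimmed mean to 500, and log2(signal + 32) was taken, so that fold changes of dim genes are understated. Probe sets with a scaled signal of at least 100 on 2 or more arrays were tested, without the 57 control probe sets, which left 19785. All 8 arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), with no block, and p-values were adjusted with the Benjamini-Hochberg method at a threshold of 0.05. Of 31042 non-control probe sets, 20826 had 1 gene symbol in the probe table of the array, 436 had several and 9780 had none, and genes were named only from probe sets with 1 symbol. The gene identifiers of 20764 probe sets matched the RefSeq gene table, and no symbol differed from it (0 updated). A gene was represented by its probe set with the highest mean log2 signal, which gave 11241 genes. Among the genes named, probe sets of Itga6, RT1-Ba, Crem, Srxn1, Rab20, Dipk2a and Id4 disagreed in sign, but none past the threshold in the opposite direction.

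Before the data were examined, 25 gene lists were fixed for cell types, junctions, matrix, signalling, stress and other processes, and so were the groups, the tests and most alternatives. The lists were tested in camera with its preset correlation of 0.01, and again with a correlation estimated per list and with fry. Lists with under 3 measured genes were not tested. With an estimated correlation camera also uses the residual degrees of freedom of the 8 arrays, which are few and fewer with a block. A call lost there does not by itself show correlation within a list. Fry tests whether the genes of a list changed, without ranking them against other genes. The counts of lists include 1 that is not described here. Symbols of a list without a probe set of 1 symbol were not analysed here. The named genes followed a fixed rule: the 8 largest rises and 8 largest falls past the threshold at 4 d and at 8 h against control, up to 4 members of each list with the largest changes past the threshold or else the member with the smallest p, and the 4 largest rises and falls between 4 d and 8 h. Transcripts without a name were passed over (1 among the falls at 4 d). Fold changes are 2 to the power of the log2 difference. Aif1 at 4 d and both probe sets of Ctsl at 8 h fall outside that rule and are named because they make up small counts, after their values were seen.

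Replicate numbers are shared between groups in the titles. The deviations of arrays from their group means correlated at 0.353 to 0.507 for arrays of the same run in different groups and at -0.476 to 0.246 for arrays of different runs, so control and 4 d arrays of the same number were paired through the shared run, while 8 h replicate 2 belonged to run 3. The run as a block was one of the alternatives for the probe sets. Because of this pairing, values from that fit are given beside those of the fit without a block. In 10 simulated data sets of 19785 probe sets with 200 changed, the fit without a block recovered 31.8% of log2 changes of 1 and 85.3% of changes of 2 at 4 d against control, and 18.7% and 81.4% at 8 h against control. With the run as a block these were 83.5%, 99.4%, 73.1% and 98.5%, with 169 false calls over the 10 sets at 4 d (8.46% of calls) and 164 at 8 h (8.72% of calls), against 1 and 0 without it. The lists were tested on simulated data too, and camera found all of 10 sets shifted by a log2 of 0.5 and none (0) of 10 unshifted ones in both comparisons. Those sets were random genes with independent noise, while the real elongating and elongated spermatid list had an estimated correlation of 0.793. The simulation therefore does not test the preset correlation for real lists. Correlation and covariance of the changes at both times were set beside 50 simulated pairs of unchanged groups that shared simulated controls. All 8 arrays were drawn as independent noise without run effects. The alternatives were other scalings, pseudocounts, signal minimums and variance models, blocks, fits of 2 groups, and leaving out each array. Figures were drawn with matplotlib 3.10.9.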

Results

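RNA from whole testes of adult Sprague-Dawley rats was measured on 8 one-colour oligonucleotide arrays. Adjudin, a compound known to detach developing germ cells from the Sertoli cells that hold them, was given once by mouth at 50 mg/kg body weight. Testes were taken 8 h later (2 arrays) and 4 d later (3 arrays), and 3 arrays held testes of untreated rats. Each of the 31099 probe sets on an array had 1 signal value, and 53.1% to 59.0% of the non-control probe sets reached a scaled signal of 100 in the controls, 51.6% to 58.8% at 8 h and 53.9% to 57.6% at 4 d. Arrays of 1 group correlated with r of 0.954 to 0.978 across probe sets. The number of arrays limited the precision. The arrays had been hybridised in 3 runs. Run 1 and run 3 each held 1 array of every group, and run 2 held 1 control and 1 array at 4 d.

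The comparison of 4 d with control addressed the changes in the testis while germ cells are lost, the subject in the series title. Among the genes that rose was Wnt4, a secreted signalling protein, from a scaled signal of 8.60 ± 3.42 to 1904 ± 123.3 (SD, n = 3 each), a 47.7-fold change on the log2(signal + 32) scale (log2 5.58, SE 0.24). Hpx, which encodes the haem-binding protein hemopexin, rose 38.3-fold, and Testin, a protein secreted by Sertoli cells, rose 36.5-fold, from 80.1 ± 23.6 to 4026 ± 582. Inhibitors of proteases rose as well: Serpina3n rose 15.8-fold and Timp1, an inhibitor of matrix metalloproteases, 15.0-fold. Among the genes that fell, Pim1, a serine/threonine kinase, went from 3407 ± 649.7 to 693 ± 58.8, and Azin2, a regulator of polyamine synthesis with high testis expression, from 10345 ± 2479.95 to 2427 ± 573.

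The other large rises were those of Gpnmb, a transmembrane glycoprotein (log2 3.31), Vgf, a neuropeptide precursor (log2 3.22), and Trim2, a ubiquitin ligase (log2 3.18). Falls past the threshold included those of P4ha3, a subunit of collagen prolyl hydroxylase (log2 -2.73), Zcchc18 (-2.54), Phospho1, a phosphatase (-2.38), Shisa8 (-2.25), Pim1 (-2.23), Pde9a, a cyclic GMP phosphodiesterase (-2.23), Azin2 (-2.08) and P2rx2, an ATP-gated channel (-1.84). The adjusted p of these 16 genes lay between 2.44e-06 for Testin and 0.0203 for Shisa8 in limma with Benjamini-Hochberg adjustment. Wnt4, Trim2, Serpina3n, Gpnmb, Vgf and Testin lay below a signal of 100 on average in the controls, as did P4ha3, Zcchc18, Shisa8 and Pde9a at 4 d. The size and order of these changes therefore depend on the added 32, while all 16 calls held with the other pseudocounts tried. The fall of Shisa8 no longer passed without control 2, control 3, 4 d 1 or 4 d 2.

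Markers of late germ cells were lower at 4 d. Of 20 measured genes of elongating and elongated spermatids, 9 fell, 0 rose and 11 did not pass; 12 fell when adjusted over the list alone, and 18 fell with the run as a block. The examples with the largest changes were Fscn3, an actin-bundling protein (log2 -1.35, SE 0.19), Prm2, a protamine that packs sperm DNA (-1.22, SE 0.27), Cabs1 (-1.07, SE 0.18) and Akap4, a protein of the sperm tail (-0.88, SE 0.18). The median log2 change of the list was -0.57, with -0.55, -0.49 and -0.68 in the 3 runs. The list ranked lower than other genes in camera (adjusted p = 9.78e-09), but adjusted p = 0.249 with an estimated correlation. In fry, which does not rank a list against other genes, its adjusted p was 0.0269. Of 16 round spermatid genes, 3 fell, namely Tssk2 (log2 -0.73) and Camk4 (-0.60), both kinases, and the transcription factor Crem (-0.48). With the run as a block 10 of them fell, and 6 fell when adjusted over the list alone. The list median was -0.39, with camera adjusted p = 0.000285, adjusted p = 0.236 with an estimated correlation and adjusted p = 0.0261 in fry. Of the 16 spermatocyte and 9 spermatogonium genes measured, 0 rose and 0 fell in limma, over all probe sets and over each list alone, and neither list passed in camera (adjusted p = 0.482 and 0.616). The smallest p in each list belonged to Piwil2 (log2 -0.32, adjusted p = 0.204) and Uchl1 (log2 0.36, adjusted p = 0.176); with the run as a block 1 spermatogonium gene, Uchl1, rose (adjusted p = 0.032).

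Genes of several somatic cell types were higher. Of 25 Sertoli cell genes, 11 rose and 1 fell (15 and 2 adjusted over the list alone, and 15 and 2 with the run as a block). Besides Testin, they included Ctsl, a cathepsin (log2 1.88), and Gstm7, a glutathione transferase (1.23), while the homeobox gene Rhox5 fell by 1.501 on the log2 scale. The Sertoli list passed in camera (adjusted p = 6.53e-06; adjusted p = 0.0465 with an estimated correlation). Of 19 genes of macrophages and other leukocytes, 12 rose and 1, Aif1, fell (16 and 1 adjusted over the list alone). The MHC class II genes RT1-Da (log2 2.36), RT1-Ba (1.53) and the invariant chain Cd74 (1.88) rose, as did the lysozyme gene Lyz2 (1.81). The leukocyte median was 1.22, with 1.23, 0.88 and 1.22 in the 3 runs (camera adjusted p = 9.78e-09; adjusted p = 0.0465 with an estimated correlation). Of 14 Leydig cell genes, 3 rose, namely Hsd11b1 (log2 1.33), Scarb1 (1.25) and Cyb5a (0.85). With the run as a block 9 rose and 2 fell, and adjusted over the list alone 5 rose and 2 fell (camera adjusted p = 0.0352; adjusted p = 0.381 with an estimated correlation). Of 13 genes of peritubular and smooth muscle cells only Myl9 rose (log2 0.84), 3 rose and 1 fell with the run as a block and also over the list alone. The list median of -0.13 and mean of 0.085 had opposite signs (camera adjusted p = 0.794). None of 10 endothelial genes passed in limma (0 over the list alone, 1 higher with the run as a block); Esam had the smallest p (log2 0.68, adjusted p = 0.115, or 0.00669 with the run as a block), and the list had a camera adjusted p of 0.120.

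**Figure D1:**
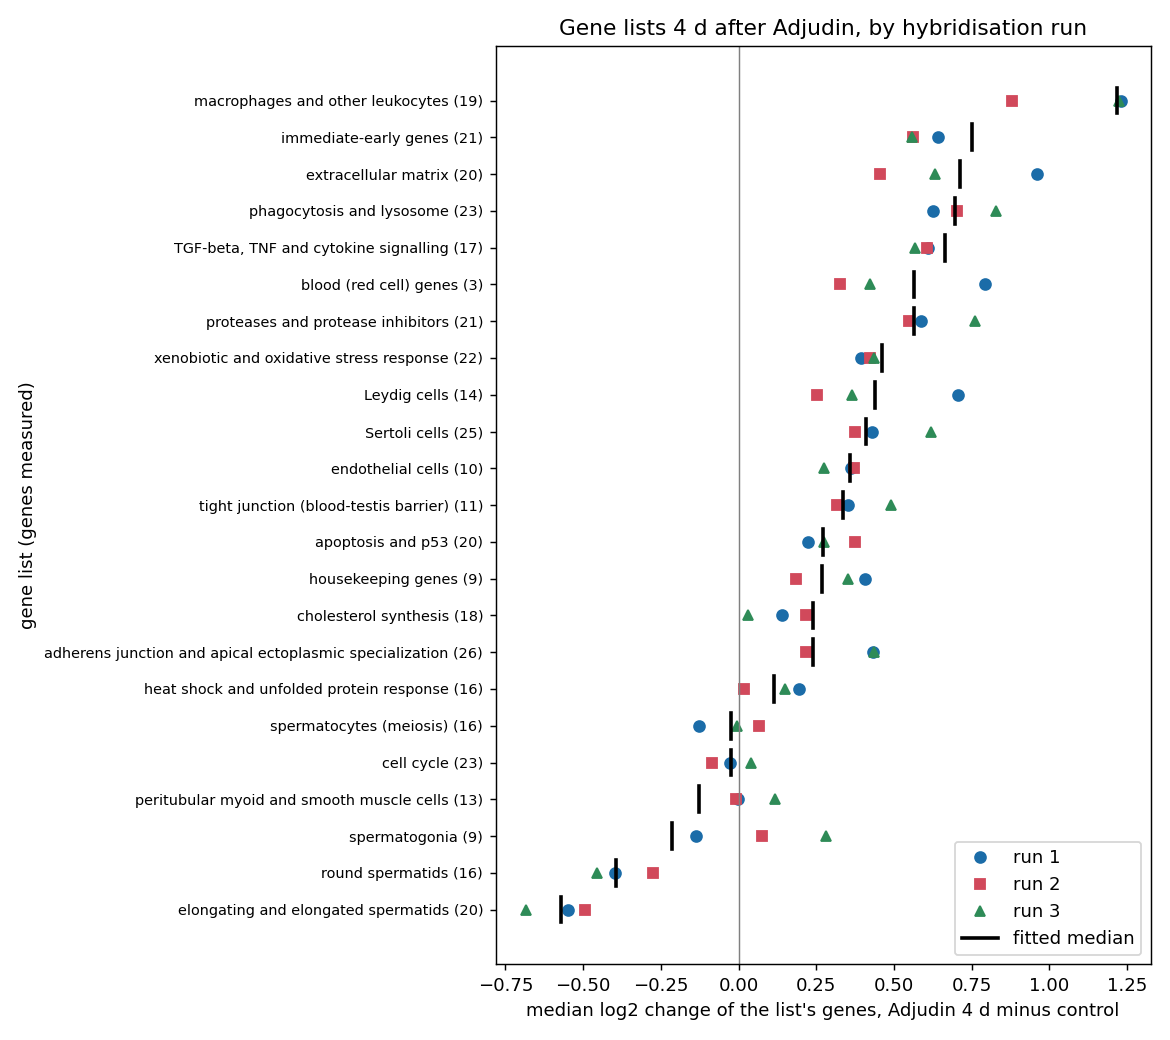
Median log2 change of the gene lists described here 4 d after Adjudin minus control (x axis), with the number of measured genes beside each list on the y axis; symbols show the median within each of the 3 hybridisation runs and black bars the median of the fitted changes over 3 arrays per group. The leukocyte list lay at 1.22 and the elongating and elongated spermatid list at -0.57, and both kept their sign in every run.

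Blood was a part of the same tissue, and 2 of 3 red cell genes rose (2 also over the list alone). Hbb, a haemoglobin chain, rose by a log2 of 1.28, with 2.19, 0.32 and 1.31 in the 3 runs, and Alas2 by 0.57; the list did not pass in camera (adjusted p = 0.144). Of the 2 measured genes of epididymis and fat, Cfd rose (log2 1.03) and Cst8 fell (-0.81), and these 2 were too few for a list test. Cst8 was bright in the controls (8136, 8293 and 8782), while Adam7, Spag11a and Defb1 of the same list did not pass the signal minimum. The fall of Cst8 therefore need not concern epididymal tissue.

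Part of the lysosome, protease and matrix genes rose at 4 d. Of 23 genes of phagocytosis and the lysosome, 12 rose and 0 fell (15 adjusted over the list alone), among them the proteases Lgmn (log2 1.63) and Tpp1 (1.44), the bridging protein Pros1 (1.33) and the glycosidase Gla (1.27), with a camera adjusted p of 1.48e-07 and adjusted p = 0.0465 with an estimated correlation. Of 21 proteases and their inhibitors, 8 rose and 0 fell, 13 rose and 1 fell with the run as a block, and 11 rose and 1 fell when adjusted over the list alone. Those with the largest rises were Serpina3n, Timp1, Serping1 (log2 2.28) and A2m (1.62), all inhibitors rather than proteases (camera adjusted p = 1.22e-06; adjusted p = 0.0465 with an estimated correlation). Of 20 extracellular matrix genes, 7 rose and 0 fell, 14 rose with the run as a block and 12 when adjusted over the list alone. They included Fbn1 (1.27), Lamc1 (1.23), Col3a1 (1.15) and Bgn (1.06), with a camera adjusted p of 3.64e-06 but adjusted p = 0.126 with an estimated correlation.

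Junction genes include those that attach germ cells to Sertoli cells. Of 26 genes of adherens junctions and the apical ectoplasmic specialization, 7 rose and 0 fell (8 over the list alone; 11 rose and 2 fell with the run as a block). They included the integrin chains Itga6 (log2 1.78) and Itgb1 (1.36) and the actin-associated proteins Actn1 (1.53) and Zyx (0.82), with camera adjusted p = 0.00515 but adjusted p = 0.126 with an estimated correlation. Of 11 tight junction genes, Cldn5 (0.91) and F11r (0.83) rose and 0 fell (4 rose and 1 fell over the list alone, and 4 and 1 with the run as a block). That list's camera adjusted p of 0.0415 became adjusted p = 0.141 with an estimated correlation and 0.0593 with the run as a block. The call was also lost with quantile normalization, with no signal minimum, with the mean of a gene's probe sets and without run 3.

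Lists of signalling, immediate-early and xenobiotic genes ranked higher too. Of 17 genes of TGF-beta, TNF and cytokine signalling, 9 rose and 0 fell (10 over the list alone), with Tnfrsf1a, a TNF receptor, at log2 2.49, Ccl2 at 1.71, Cxcl1 at 1.57 (not past the threshold with the largest pseudocount tried) and Nfkb1 at 1.51 (camera adjusted p = 4.15e-05; adjusted p = 0.0465 with an estimated correlation). Of 21 immediate-early genes, 10 rose and 0 fell, 10 rose and 1 fell over the list alone, and 11 rose and 2 fell with the run as a block. Ier3 (1.93), Ier2 (1.78), Gadd45b (1.19) and Gadd45a (1.12) were among them (camera adjusted p = 0.00107; adjusted p = 0.0465 with an estimated correlation). Ccl2, Cxcl1, Ier2 and Gadd45b lay below a signal of 100 on every control array, so the size of their rises depends on the added 32. Of 22 xenobiotic and oxidative stress genes, 7 rose and 0 fell, 9 rose over the list alone, and 14 rose and 2 fell with the run as a block. Gstp1 (1.97), Gpx1 (1.59), Srxn1 (1.28) and Nqo1 (0.89) rose, with camera adjusted p = 0.000114 and adjusted p = 0.0465 with an estimated correlation.

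Of 20 apoptosis and p53 genes, Casp6 (log2 1.99), Ccng1 (1.41) and Bid (0.97) rose and 0 fell (4 rose over the list alone, 6 with the run as a block). Their camera adjusted p of 0.0443 became adjusted p = 0.189 with an estimated correlation and 0.0694 with the run as a block. Casp6 lay below a signal of 100 on every control array, so the size of its rise depends on the added 32. Of 9 housekeeping genes, B2m (1.17), Pgk1 (0.80) and Hprt1 (0.60) rose and 0 fell (3 over the list alone, 5 with the run as a block), with camera adjusted p = 0.0458 and adjusted p = 0.371 with an estimated correlation; that list did not pass after median scaling. Of 16 heat shock genes, Hspe1 (1.04) and Hspd1 (0.87) rose and 0 fell, 2 rose over the list alone, and 4 rose and 3 fell with the run as a block (camera adjusted p = 0.547; the list median of 0.11 was negative after median scaling). Of 18 cholesterol synthesis genes, Msmo1 (0.70) rose and 0 fell, 1 rose over the list alone, and 4 rose and 1 fell with the run as a block (camera adjusted p = 0.310). Of 23 cell cycle genes, Bub1 (-0.55) fell and 0 rose, 1 fell over the list alone and 5 with the run as a block (camera adjusted p = 0.266).

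In all, 1218 probe sets were higher and 738 lower at 4 d among 19785 tested, at an adjusted p below 0.05 in limma. Of these, 604 and 203 changed by at least 2-fold. All 1956 moved in the same direction in each of the 3 runs. They were selected on these same arrays, which favours such agreement, so it adds no separate support. With the run as a block 2632 were higher and 1819 lower, including all 1956. The share that was higher, 62.3%, was 53.5% after quantile normalization (1135 higher, 986 lower) and 44.6% after equalising medians (743 higher, 923 lower). Equalising medians moved the median log2 change of all tested probe sets from 0.036 to -0.10. Without 4 d replicate 1 there were 580 higher and 315 lower, without 4 d replicate 3 702 and 485, without control 2 767 and 412, and without control 1 453 lower. Of 24 lists tested in camera 14 were higher and 2 lower. Of these, 7 held with an estimated correlation and 0 held with an estimated correlation and the run as a block. The tight junction call was lost although its estimated correlation of -0.024 lay below the preset 0.01. These losses therefore do not show correlation within lists alone. Up to 13 lists also passed in camera with its preset correlation when the same 6 arrays were divided in other ways, with both groups mixed unequally on each side. Such divisions kept part of the real difference, so they set no chance level. In fry the spermatogonium, spermatocyte, peritubular, heat shock and cell cycle lists did not pass at 4 d (adjusted p = 0.474, 0.595, 0.528, 0.0576 and 0.307). Every other list tested passed, among them the matrix (0.00490), adherens junction (0.00254), tight junction (0.00291) and endothelial (0.0155) lists.

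The comparison of 8 h with control addressed the early response to the same dose. A few inflammatory and immediate-early genes rose. Cxcl1, a chemokine that attracts neutrophils, went from a scaled signal of 19.8 ± 14.1 (SD, n = 3) to 948 ± 30.6 (SD, n = 2), a 19.4-fold change on the log2(signal + 32) scale (log2 4.28, SE 0.43). The transcription factors Fos and Egr1 rose 7.94-fold and 6.84-fold, Ier3, an early stress-response gene, 7.72-fold and the cytokine Il1a 6.76-fold. Dipk2a (log2 1.89), Rab20, a small GTPase (1.63), and Ppp1r15a, a regulatory subunit of a phosphatase (1.60), also rose. The adjusted p of these 8 genes lay between 0.00245 and 0.0188 in limma. The integrin gene Itga6 rose by a log2 of 1.51 (adjusted p = 0.0206). Cxcl1 and Fos lay below a signal of 100 in the controls, so their fold changes depend on the added 32, and Fos did not pass at 8 h with a pseudocount of 4.

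**Figure D2:**
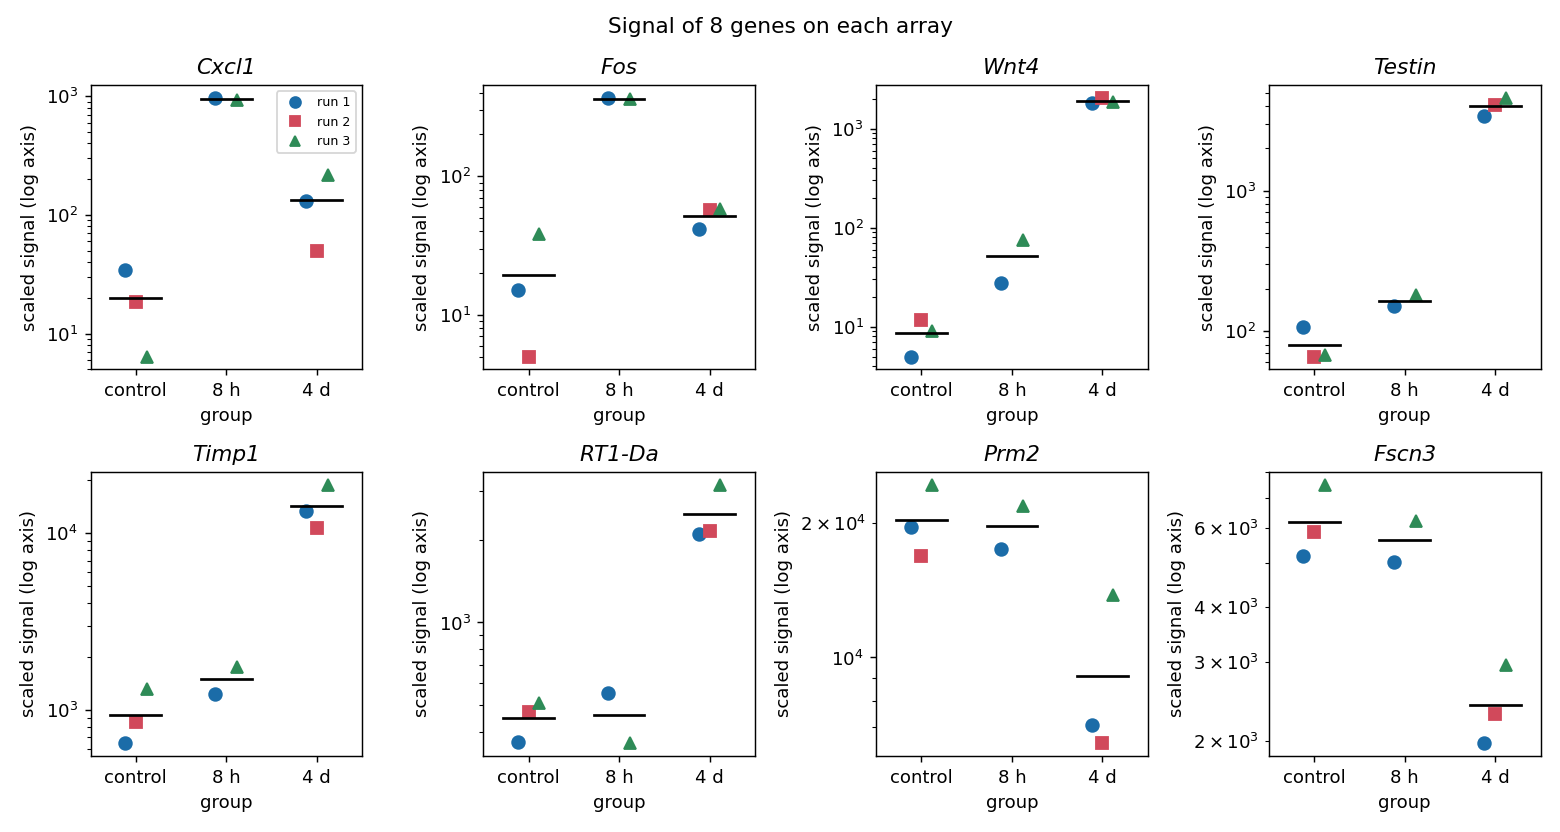
Scaled signal (y axis, log scale) of 8 genes on each of the 8 arrays by group (x axis); symbols mark the hybridisation run and black lines the group mean. Cxcl1 averaged 19.8 in the controls, 948 at 8 h and 133 at 4 d, while Testin averaged 80.1, 165 and 4026.

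Of 21 immediate-early genes 3 rose and 0 fell at 8 h over all probe sets, and 14 rose when adjusted over the list alone; 5 rose with the run as a block. The list median was a log2 of 0.85, with 0.84 in run 1 and 1.02 in run 3, and the list passed in camera (adjusted p = 4.26e-30; adjusted p = 0.00123 with an estimated correlation). Of 17 genes of TGF-beta, TNF and cytokine signalling 2 rose, Cxcl1 and Il1a, and 0 fell; 6 rose over the list alone and 5 with the run as a block (camera adjusted p = 2.66e-14; adjusted p = 0.00895 with an estimated correlation, 0.183 with the block as well). Of 26 adherens junction genes Itga6 rose and 0 fell, 4 rose over the list alone, and the camera adjusted p of 0.00123 became adjusted p = 0.181 with an estimated correlation. The proteases and inhibitors (21 genes, 0 rose and 0 fell, 2 higher over the list alone, 1 higher with the run as a block; camera adjusted p = 0.0145) and the xenobiotic genes (22 genes, 0 rose and 0 fell, 0 over the list alone, 1 higher with the run as a block; camera adjusted p = 0.0248) likewise gave adjusted p = 0.326 and adjusted p = 0.239 with an estimated correlation. The member with the smallest p was Plat (log2 1.21, adjusted p = 0.112, or 0.0144 with the run as a block) in the first of these and Cyp1b1 (0.59, adjusted p = 0.762) in the second.

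No gene of the germ cell, Leydig, peritubular, endothelial, leukocyte or blood lists passed over all probe sets at 8 h in limma (0 of each list; 773 of all 19785 probe sets had an unadjusted p below 0.05). The leukocyte list had a median of 0.13 (19 genes, camera adjusted p = 0.519). The elongating and elongated spermatid list had one of -0.0021 with a mean of 0.0011 (20 genes, camera adjusted p = 0.977; lower with an adjusted p of 0.00983 with the run as a block, and adjusted p = 0.610 with that block and an estimated correlation). In the Leydig list 2 of 14 genes were lower when adjusted over the list alone; Cyp11a1, the first enzyme of steroid synthesis, had the smallest p (log2 -0.97, adjusted p = 0.356). Of 20 apoptosis genes 2 were higher when adjusted over the list alone. Mcl1, an apoptosis inhibitor, had a log2 of 1.07 (adjusted p = 0.281; 0.036 with the run as a block). Among 25 Sertoli cell genes Testin was at 0.83 (adjusted p = 0.446). The brighter probe set of Ctsl was at 0.56 and passed only with the run as a block (adjusted p = 0.0335), while its other probe set passed without it (log2 1.21, adjusted p = 0.0112). Among 23 lysosome genes Lgmn was at 0.59 (adjusted p = 0.446). In each remaining list the member with the smallest p had an adjusted p of 0.878 (Atf4, log2 0.48) or above: Sycp2 (0.42), Id4 (0.34), Zpbp (0.21), Cabs1 (0.18), Csf1r (-0.36), Actg2 (0.73), Tie1 (-0.87), Slc4a1 (-0.22), Cfd (0.29), Jam3 (0.69), Mgp (0.39), Dhcr7 (-0.56), Mki67 (-0.33) and Pgk1 (0.27).

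In total 13 probe sets, 2 of them without a gene name, were higher at 8 h and 0 were lower; the run as a block gave 53 higher and 2 lower, including all 13. Without either of the 2 arrays at 8 h none passed (0 higher), and without run 3 the counts were 5 higher and 1 lower. In camera 5 lists were higher and 0 lower, 2 with an estimated correlation, 8 higher and 1 lower with the run as a block, 8 higher without 8 h replicate 1, and 3 higher and 1 lower without 8 h replicate 2. The Sertoli and tight junction lists (adjusted p = 0.0998 and 0.0767) were among those gained with the block (0.0334 each), and 1 list, the immediate-early genes, held with the block and an estimated correlation (adjusted p = 0.0379).

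The comparison of 4 d with 8 h was the direct test of the difference between both times. Genes that rose from 8 h to 4 d included Wnt4 (log2 4.60), Testin (log2 4.36), Serpina3n (3.68) and Hpx (3.58). Genes that fell included Cxcl1 (log2 -2.71), Zcchc18 (-2.69), Egr1 (-2.27) and Fos (-2.24), and the adjusted p of these 8 genes lay between 3.87e-05 and 0.00765 in limma. Wnt4 and Serpina3n at 8 h, and Zcchc18 and Fos at 4 d, lay below a signal of 100 on average, so the size of their changes depends on the added 32. Of 21 immediate-early genes 5 fell and 0 rose from 8 h to 4 d (8 and 1 over the list alone, 7 and 1 with the run as a block; camera adjusted p = 0.00131; adjusted p = 0.0882 with an estimated correlation). Of 20 elongating and elongated spermatid genes 8 fell and 0 rose (12 over the list alone, 19 with the run as a block), and of 19 leukocyte genes 8 rose and 0 fell, with 14 higher and 1 lower over the list alone and 11 and 1 with the run as a block (camera adjusted p = 4.23e-09 and 3.37e-08; adjusted p = 0.311 and 0.0651 with an estimated correlation). Altogether 709 probe sets were higher and 489 lower at 4 d than at 8 h, and 1695 and 1403 with the run as a block. The share that was higher, 59.2%, was 49.4% after quantile normalization (635 and 651) and 45.2% after equalising medians (401 and 487). Without 8 h replicate 2 the counts were 174 higher and 90 lower, without 8 h replicate 1 258 and 140, without 4 d replicate 1 262 and 154, without 4 d replicate 2 404 and 306, and without 4 d replicate 3 395 and 324. In camera 8 lists were higher and 3 lower, of which 0 held with an estimated correlation. The housekeeping list was also higher with the run as a block (adjusted p = 0.0189, but adjusted p = 0.277 with an estimated correlation as well).

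**Figure D3:**
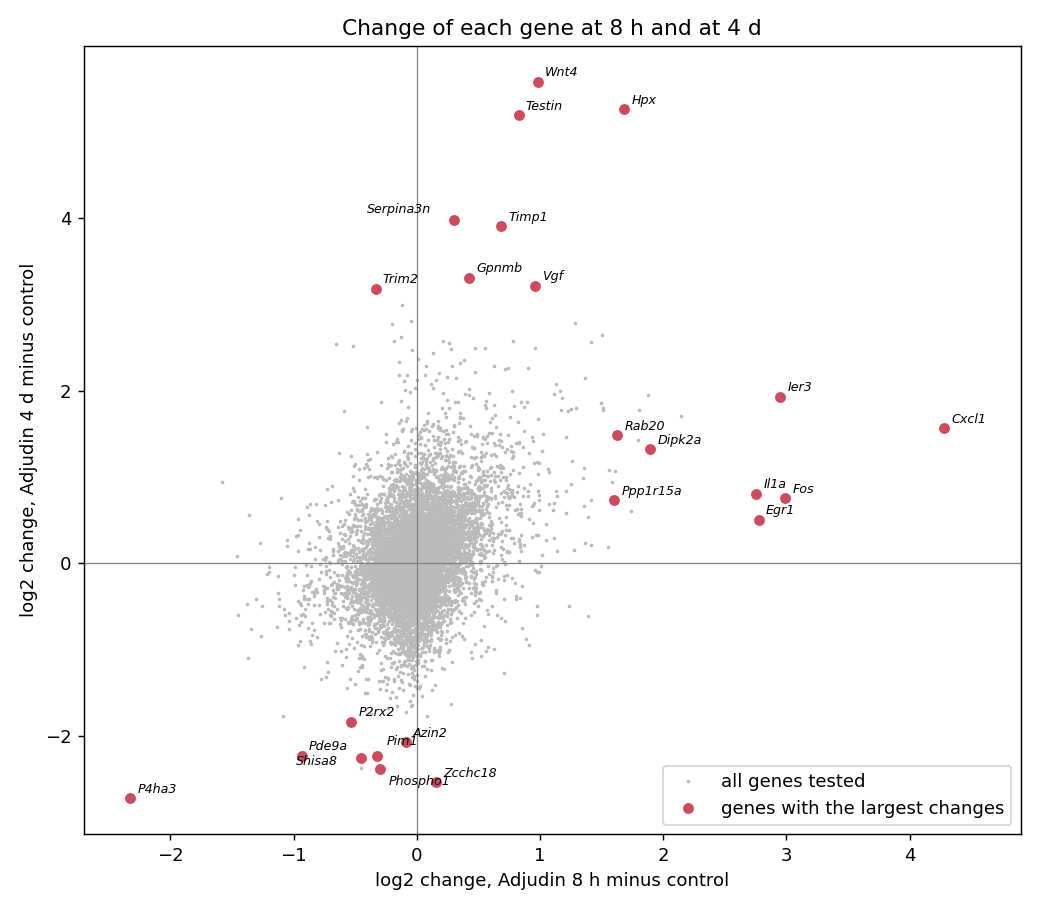
Log2 change against control at 8 h (x axis) and at 4 d (y axis) for every gene tested (grey) and for the genes past the threshold at either time with the largest changes on the log2(signal + 32) scale (red). Cxcl1 lay at 4.28 and 1.57, Wnt4 at 0.98 and 5.58.

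Both times were set against the same 3 controls, which alone makes their changes correlate. Over the 19785 probe sets the Pearson correlation of the log2 changes at 8 h and at 4 d was 0.356. This is across probe sets, which are not independent replicates. Simulated unchanged groups that shared simulated controls had a mean of 0.449. The covariance was 0.0513 against a simulated 0.0343. The simulations held neither run effects nor real changes, so neither difference shows how far both times agreed. Of the 13 probe sets higher at 8 h, 9 were also higher at 4 d, among them those of Cxcl1, Il1a, Ier3, Dipk2a, Rab20, Ppp1r15a, Itga6 and Ctsl, where independent lists of these lengths would share 0.800. With 3 controls no division into separate sets of 2 was possible, so part of the overlap may come from the shared controls. The simulated unchanged groups had no probe set higher at 1 of the times or at both, so they set no level for this overlap, and none was computed for the fit with the block. With the run as a block 40 of 55 probe sets past the threshold at 8 h passed in the same direction at 4 d, 2 passed in the opposite direction and 21 fell from 8 h to 4 d.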

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

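Of the tests in this part, only the divisions of the 6 control and 4 d arrays were chosen before the results were seen; the tests of scaling, run, cell share, leukocyte markers, handling and RNA quality were chosen after.

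The changes at 8 h and at 4 d differed, in the direct limma test, for 1198 probe sets. Among lists, the median log2 difference of 4 d minus 8 h was 0.95 for leukocytes, 0.78 for extracellular matrix, 0.62 for lysosome, 0.53 for proteases and inhibitors, 0.49 for Leydig cells, 0.40 for Sertoli cells and 0.33 for xenobiotic genes. It was -0.60 for elongating and elongated spermatids, -0.43 for round spermatids and -0.22 for immediate-early genes. These lists passed in camera with its preset correlation and 0 of them with an estimated correlation (smallest adjusted p = 0.0651, leukocytes).

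Among the genes named for the largest changes, those higher at 4 d than at 8 h by that test were Wnt4 (log2 difference 4.60), Testin (4.36), Serpina3n (3.68), Hpx (3.58), Trim2 (3.51), Timp1 (3.22), Gpnmb (2.88) and Vgf (2.26). Lower at 4 d than at 8 h among them were Cxcl1 (-2.71), Zcchc18 (-2.69), Egr1 (-2.27), Fos (-2.24), Phospho1 (-2.08), Azin2 (-1.99), Il1a (-1.95), Pim1 (-1.91), P2rx2 (-1.30), Pde9a (-1.29), Ier3 (-1.02) and Ppp1r15a (-0.87). Of 81 other named list members, 44 also differed between 4 d and 8 h. With the run as a block, Fabp3, a fatty acid binding protein, was lower at 8 h and higher at 4 d against control (difference 1.07), and Dusp5, a phosphatase, was higher at 8 h and lower at 4 d (difference -2.09).

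The 3 GAPDH control probe sets, outside the tested set, had a mean signal at 4 d of 1.49, 1.56 and 1.35 times that of the controls, for the 3' end, the 5' end and the middle of the transcript. Every array at 4 d lay above every control, which chance gives for 10% of probe sets in either direction at 3 against 3; after median scaling this held for the ends but not for the middle (1.21). No group has 4 or more arrays, so no array was tested for standing apart. The arrays of run 3 differed descriptively. Control 3, 8 h 2 and 4 d 3 had the lowest shares of probe sets at a scaled signal of 100 in their groups (53.1%, 51.6% and 53.9%). Array weights were 0.390 for control 3 and 0.552 for 4 d 3, lower than for every other array.

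The leukocyte and Sertoli lists ranked higher at 4 d, also with an estimated correlation (adjusted p = 0.0465 each) but not with that and the run as a block (0.149 and 0.188), while the Leydig list did so with the preset correlation and the peritubular and endothelial lists did not pass. A lower share of germ cells raises the genes of all somatic types alike, if germ cells do not express them, which was not checked. The leukocyte median exceeded that of the peritubular muscle list, the lowest of the somatic lists, by 1.35 (permutation p = 0.00011, two-sided, over genes). That p treats genes as independent and does not measure the spread between samples. The Sertoli, Leydig and endothelial medians lay close together, at 0.41, 0.44 and 0.36. The leukocyte median thus lay above those of the other somatic lists, but only the peritubular list was set against it in a test. That pair was chosen after the results were seen, so it cannot decide the cause. Scaling moves all genes by 1 amount, and the leukocyte median lay at percentile 100 of 10000 random lists matched on size and signal. That comparison repeats the camera ranking on the same data, for a list already known to rank high, so it adds no separate support. The run as the cause is opposed by a lowest median within a run of 0.88. A change in leukocyte number or activity after the drug may contribute, as a hypothesis, and a part played by the germ cell share stays open.

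Cxcl1, Il1a and 3 of 21 immediate-early genes rose at 8 h, and the immediate-early list ranked higher. Entry of leukocytes would raise their markers too, and the median of the measured markers was 0.16 (95% bootstrap interval over genes -0.14 to 0.40). That interval leaves out the spread between arrays. These are 10 of 24 listed, judged too few to exclude entry, but as a set they showed no clear rise. The other markers on the array stayed near background on every array. Among them S100a8 and S100a9 had means of 17.6 and 21.1 in the controls and 2.70 and 14.4 at 8 h, while Csf3r and Camp had higher means at 8 h. The measured markers gave no sign of a large entry, but they cannot exclude it, so entry is left open. Handling, gavage or vehicle cannot be told apart from the drug, since no handled group exists beside the median of 0.85 for the immediate-early list. A response of testis cells to the drug also stays open.

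Of 20 late spermatid genes 9 fell at 4 d, and the list ranked lower in camera but not with an estimated correlation (adjusted p = 0.249). Their median lay at or below percentile 0.1 of 2000 matched random lists under all 3 scalings (median -0.73 to -0.35). The fall relative to other genes thus did not depend on which of these scalings was used. Setting the list against random lists repeats the camera ranking on the same data and adds no separate support. Lower RNA quality would raise the 3' to 5' ratio of control transcripts at 4 d. The ratio's mean log2 difference was -0.050 (SD 0.030 over 3 runs), and 8 of 9 differences were lower at 4 d, the opposite direction. The ratios thus give no sign of lower quality at 4 d. Their mean lay within 2 SD of 0, the limit used for this test, so RNA quality is left open. Loss of these cells and lower transcription in them could both give the fall and were not told apart by any test here.

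For the counts at 4 d against control, the 6 arrays can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real division gave 1956 probe sets and was the only 1 of 10 to reach that number (highest other 0). It gave 16 lists, again 1 of 10, with 13 as the highest other, and that division parted as many pairs of the same run as the real one. The other divisions mixed both groups unequally on each side and so kept part of the real difference. Their counts therefore set no chance level.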

How the results depend on the processing

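The run as a block for the lists and for the overlap, median scaling for the lists and the fits without run 3 were added after seeing the data; the other alternatives were chosen before the data were examined. Over all alternatives, values of named genes kept direction and side of the threshold 2347 times, lost the call 188 times, gained it 8 times and moved 2 times; those of single lists did so 1081, 62, 32 and 47 times, and 2 reversed. The cause of the differences below was not tested, except that fewer arrays or genes or an added block changes the test by construction. Median scaling gave 743 probe sets higher at 4 d against control and 401 at 4 d against 8 h. A pseudocount of 4 gave a covariance of 0.0817, and the largest pseudocount tried gave 0.0247 and 1 probe set lower at 8 h. With no signal minimum 8 lists were higher at 8 h. Without a trend 289 probe sets were lower at 4 d against 8 h. Array weights gave 1918 higher and 1254 lower at 4 d. A fit of only 2 groups gave 7 higher at 8 h. The replicate number as a block gave 2118 higher and 1376 lower at 4 d, 36 and 2 at 8 h with 8 lists higher, and 1492 and 1053 at 4 d against 8 h. The run as a block gave 2632 and 1819, 53 and 2, and 1695 and 1403, with 8 lists higher and 1 lower at 8 h and 40 probe sets higher at both times. An estimated correlation left 7 lists higher and 0 lower at 4 d, 2 higher at 8 h, and 0 higher and 0 lower at 4 d against 8 h; fry gave 2 higher at 8 h. Without run 3 the 8 h counts were 5 higher and 1 lower, with 2 lists higher. The median of elongating and elongated spermatid genes at 8 h, -0.0021, ranged from -0.172 without 8 h replicate 2 to 0.188 without 8 h replicate 1, and was -0.0825 with the run as a block. Leaving out 1 array gave 580 to 1136 higher and 315 to 667 lower at 4 d; 0 to 14 higher and 0 to 1 lower at 8 h, with 3 to 8 lists higher and 0 to 1 lower; and 174 to 875 higher and 90 to 626 lower at 4 d against 8 h. Without 8 h replicate 1 or 2 no probe set passed at 8 h, and the remaining array was assumed to vary like the other groups. Genes near background are limited by the signal minimum of 100.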

Other observations

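Members of other gene families also passed at 4 d against control; the 22 families were formed by gene symbol and tested after the data were seen. Cathepsins, lysosomal proteases, rose in 8 of 12 genes and fell in 0 (Ctsl 1.88, Ctsa 1.87). Annexins, calcium-dependent membrane-binding proteins, rose in 8 of 9 (Anxa2 1.60), in 7 after quantile normalization and in 5 after median scaling. Complement components rose in 5 of 10 (C1s 2.29, C1r 1.52). S100 proteins rose in 5 of 10 (S100a11 2.77, S100a4 2.55), in 3 after median scaling. Of 25 interferon-induced genes 9 rose (Gbp7 2.26, Gbp2 2.26, Isg15 1.57) and Isg20 fell (-0.65). Of 37 proteasome subunits 3 rose, the immunoproteasome subunits Psmb9 (0.99), Psmb8 (0.79) and Psmb10 (0.78), while 13 rose and 2 fell with the run as a block, 5 rose after quantile normalization and 2 after median scaling, where the family median turned to -0.0052; the family did not pass in camera (adjusted p = 0.0543). Of 14 Spata genes, named for roles in sperm formation, 3 fell (11 with the run as a block, 7 after quantile normalization, 1 after median scaling), and all 14 were negative under each of the 3 scalings. In camera 9 families were higher and 2 lower with the preset correlation, and 0 passed with an estimated correlation (smallest adjusted p = 0.128). That second form of the test has few residual degrees of freedom here, so this loss does not show correlation alone. At 8 h no family member passed in limma at the gene level without a block (0 of each).

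The family membership was changed once after values were seen: Isg20l2, 5 ribosomal protein kinases and 1 pseudogene, which share a symbol stem but not the function, were taken out. Before that, the interferon family had 26 genes with 9 higher and 2 lower, and the ribosomal proteins had 49 with 3 higher and 0 lower, against 43 with 2 higher and 0 lower after it (9 and 1 with the run as a block).

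Of 24 leukocyte and neutrophil markers listed after the data were seen, 17 matched a gene, 10 were measured, 7 also stood in the fixed leukocyte list, and 6 rose at 4 d. Lcn2 was at a log2 of 0.21 at 8 h and rose by 2.58 at 4 d. The abundant neutrophil genes S100a8 and S100a9 stayed below the signal minimum on every array, with means of 17.6 and 21.1 in the controls, 2.70 and 14.4 at 8 h, and 20.5 and 29.9 at 4 d.

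Hexokinase control probe sets had a mean at 4 d of 0.578, 0.612 and 0.569 times that of the controls and stayed below 1 under the other scalings. Those of actin were at 0.914, 0.951 and 0.862, and at 1.07, 1.10 and 1.02 after quantile normalization.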
